A study of Nostoc sp. PCC 7120 = FACHB-418 with 24 samples.

How the data were processed

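RNA was measured in Anabaena sp. PCC 7120, a filamentous cyanobacterium that differentiates nitrogen-fixing heterocysts when combined nitrogen is removed. There were 24 libraries in 6 groups of 4: the wild type (WT), strain CSVM34 with sepJ deleted, and strain CSVM141 with sepJ, fraC and fraD deleted, each after 18 h in medium with nitrate or in the same medium without combined nitrogen. Per the labels' protocols, 50 ml cultures were started from washed filaments, ribosomal RNA was depleted, and single-end reads of 60 bases were taken on a HiSeq 2500. Per the labels, each sample gave between 9.3M and 13M reads. The depth of each single library is unknown, because the table holds no raw counts. Groups were taken from the sample titles. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

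Per the submitters' processing notes, the authors used cutadapt, Bowtie2, HTSeq, DESeq and DESeq2. Their versions, the genome build and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of 6051 rows. Per the file headers, it holds a log2 expression value for each library from the regularized log transformation of DESeq2, which pulls the values of genes with few reads toward the mean of that gene over all libraries. Per the file headers, the authors also deposited 9 comparisons of 2 groups. Each gives a log2 fold change with its standard error, a p-value, an adjusted p-value, a test statistic and a mark for called genes. The statistic is a score of the authors that was taken here as the fold change over its standard error, as in DESeq2. The deposited mean normalized count is a signal of the authors that was taken as counts divided by size factors and averaged over all libraries, as in DESeq2. The file headers name both columns but do not say how they were made. The median of the mean normalized counts was 84.0 over tested genes, and the 10 highest genes held 29.4% of their sum of 2.22e+06. All the authors' values printed here are named as such.

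Of the 6051 rows, 58 had a mean count of 0, which left 5993 genes tested. Identifiers were matched to the RefSeq gene table of assembly ASM970v1, used for names and for which genes neighbour each other. Of the identifiers, 4831 matched a locus tag, 217 matched a symbol and 1003 matched neither. No coordinates are printed, because the build of the table is not named. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart, and near-identical copies such as the psbA genes can share reads. Some symbols are also carried in the reference by another locus with no row of its own. Among them are nifH, psaB, psbD, apcB, petC, petJ, atpC, atpD, atpE and atpH. Which locus such a row counts is not known.

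The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. The planned test was a negative binomial test on raw counts, or limma on log2 values with a pseudocount of 1 where a table held none. The deposited values were taken to be on a log2 scale already, so limma 3.58.1 in R 4.3.3 was fitted to them as deposited, with a mean-variance trend and a pseudocount of 0. All 24 libraries entered 1 fit of 6 group means with 18 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 with no minimum fold. All adjusted p-values of single genes printed here come from limma, and all of lists from camera in limma. The log2 differences printed as such are on the regularized scale, which understates changes. Over genes with a mean normalized count of at least 200, their slope on the authors' deposited log2 fold changes was between 0.450 and 0.671.

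There were 18 gene lists with at least 3 measured members: septum and intercellular transport, nitrogenase, heterocyst regulators, heterocyst glycolipid layer, heterocyst polysaccharide layer, heterocyst oxidases and hydrogenase, nitrate and ammonium assimilation, inorganic carbon uptake, carboxysome and CO2 fixation, photosystem I, photosystem II, phycobilisome, electron transfer and ATP synthase, cell division and elongation, iron limitation, stress and oxidative defence, ribosomal proteins, and peptidoglycan synthesis. The last was written after the table was seen, since the planned peptidoglycan and transposase lists searched product text, which the table lacks. Some planned members had no row of their own or stood for another gene in the reference, among them 6 of the 13 inorganic carbon uptake genes and 5 of the 9 oxidase and hydrogenase genes. These 5 were all the cytochrome oxidase genes of that list, which left the flavodiiron genes flv1B and flv3B and the hydrogenase genes hupS and hupL. Each list was tested with camera with the correlation between genes estimated, adjusted over the 18 lists of a comparison. Alternatives were a preset correlation of 0.01 and fry.

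Genes named in the text were chosen by a rule set before the data were examined. It takes the 6 genes at or next to the deletions in every group, and the 8 largest rises and falls of each comparison against WT or between media. These are taken among called genes with a mean above the median of the table and no overlap between the 4 and 4 values. In comparisons of CSVM141 with CSVM34, and in differences between responses, the 5 largest each way are taken. For the differences between responses, the criterion of no overlap could not be applied. Of each list described, the 2 members with the smallest p in each direction are named. Any other gene named was chosen after its values were seen.

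Alternatives were a minimum log2 difference of 1, only the libraries of the groups compared, a filter at the 10th percentile of the mean, a block, and leaving out each library in turn. Chosen after seeing the data were the authors' deposited adjusted p-value, a minimum mean normalized count of 20, limma without the trend, libraries centred on their medians, and leaving out plasmid genes. The search for runs of neighbouring plasmid genes was also chosen after the data were seen. It used the authors' deposited fold changes of at least 8 with an adjusted p below 0.05 in both media, a mean normalized count of at least 10 and at least 3 consecutive genes. Percentages of the WT level are the ratios given by these fold changes. Derived from all comparisons, 99.3% of the 23972 sums of fold changes around closed loops of groups closed within 0.01 log2.

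Among the 36 pairs of libraries within a group, the SD of the differences was between 0.156 and 0.413 log2, and no pair held identical values. On data simulated for the WT comparison between media over 5993 genes, the test recovered 80.6% of genes changed by 0.5 log2, 98.5% of those changed by 1 and 98.5% of those changed by 2, with 5 false calls among 5793 genes. The changed genes were drawn only from those with a mean above the median. Noise was independent between genes, with the same spread in all groups. Recovery of genes with lower means, or under correlated or uneven noise, was not tested. Of 12 simulated contrasts with no change, the largest number of calls was 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.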

Results

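The transcriptomes of the wild type and of strains lacking septal proteins were compared with nitrate and 18 h after its removal. SepJ, FraC and FraD sit at the septa between the cells of a filament and are needed for molecules to pass between them. The 24 libraries fell into 6 groups of 4, from 3 strains in 2 media, and per the labels each gave between 9.3M and 13M reads. Values are regularized log2 expression, so differences are in log2 and understate changes. Library medians lay between 6.28 and 6.40.

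The deleted genes were examined first. With nitrate, sepJ was at 8.41 ± 0.13 in WT, 5.96 ± 0.12 in CSVM34 and 5.96 ± 0.22 in CSVM141 (SD, n = 4 each). Without nitrate, sepJ was at 9.00 ± 0.06 in WT, 6.33 ± 0.05 in CSVM34 and 6.17 ± 0.25 in CSVM141 (SD, n = 4 each). In nitrate medium, fraD was at 6.41 ± 0.10 in WT, 6.06 ± 0.39 in CSVM34 and 4.79 ± 0.26 in CSVM141, and fraC at 5.31 ± 0.25, 5.13 ± 0.22 and 4.34 ± 0.26 (SD, n = 4 each). Without nitrate, fraD was at 6.47 ± 0.13, 6.52 ± 0.08 and 4.96 ± 0.22, and fraC at 5.47 ± 0.17, 5.37 ± 0.16 and 4.54 ± 0.11 in the same order (SD, n = 4 each). In the authors' deposited table, sepJ was lower than in WT by 13.7-fold in CSVM34 and 14.2-fold in CSVM141 with nitrate, and in CSVM141 fraD by 11.2-fold and fraC by 5.58-fold with nitrate (7.55-fold and 3.70-fold without). Of the neighbouring genes with nitrate, fraE was at 7.46 in WT, 7.25 in CSVM34 and 7.20 in CSVM141, fraF at 7.69, 7.49 and 7.76, and hetR at 10.35, 10.40 and 10.11. Without nitrate, in the same order, fraE was at 7.93, 8.04 and 8.12, fraF at 8.56, 8.59 and 8.74, and hetR at 10.71, 10.74 and 10.54. Of 24 libraries, 0 had a level of sepJ that went against the strain label.

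**Figure D1:**
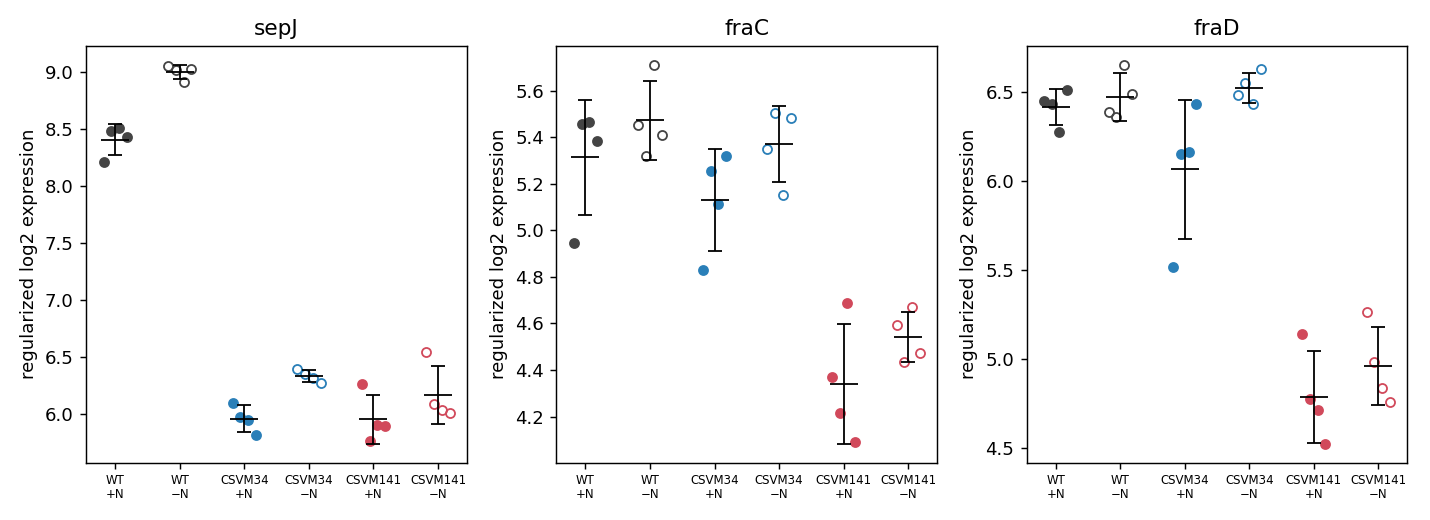
Regularized log2 expression of sepJ, fraC and fraD in each library (points) with group mean and SD (bars, n = 4), with nitrate (+N, filled) and without (−N, open). sepJ is lower in both mutants, and fraC and fraD are lower in CSVM141.

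Removal of nitrate from WT shows the response of the parent strain. Genes of the heterocyst polysaccharide layer, which forms the outer envelope of these cells, rose most. Of 19 measured, 17 rose and none fell, with a median difference of 2.51, and 17 rose when adjusted over the list alone (camera adjusted p = 0.0103). All of them but hepB, hepK and hepN are neighbours, from alr2825 to alr2841, so counts over this list are not of independent genes. On the regularized scale, among the largest rises were alr2827 at 4.18 (SE 0.27, limma adjusted p = 1.03e-11), alr2833 at 4.17, alr2825 (rfbF) at 3.83, alr2828 at 3.59, alr2829 at 3.38 and hepA at 2.87. Among the largest falls were the light-harvesting phycoerythrocyanin genes. pecA was at 10.10 ± 0.32 without nitrate and 13.62 ± 0.25 with it (SD, n = 4 each), a difference of -3.52 (SE 0.17, limma adjusted p = 1.03e-13). pecB fell by 3.48, pecC by 3.18, pecE by 2.88, pecF by 2.15, and nrtD of the nitrate transporter by 2.21. All 20 phycobilisome genes fell (20 adjusted over the list alone, median -1.80, camera adjusted p = 0.0166).

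Photosynthetic genes fell along with them. All 10 photosystem I genes fell (10 adjusted over the list alone, median -0.60, camera adjusted p = 0.0103), among them psaL at -0.66 and psaJ at -0.60. Of 16 photosystem II genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.75, camera adjusted p = 0.0103), with psbT at -1.05 and psbV at -1.32, while psbAIII, which encodes a D1 reaction centre protein, was higher by 0.76. Of 14 heterocyst regulators, 9 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.48, camera adjusted p = 0.0349), with nrrA at 2.20, hetC at 1.83, patA at -0.74 and patN at -0.23. The call of this list was lost without CSVM141 with nitrate replicate 1 (camera adjusted p = 0.0549).

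The other lists were not called by camera in WT, although members were. Of 14 glycolipid layer genes 9 rose (12 adjusted over the list alone, camera adjusted p = 0.0646), with devA at 1.52 and hglD at 0.97, and of 17 nitrogenase genes 8 rose (8 adjusted over the list alone, camera adjusted p = 0.0646), with hesA at 1.87 and nifV1 at 1.30. Many nitrogenase genes had few reads. The authors' mean normalized counts were 20.8 for nifH, 9.73 for nifD and 5.63 for nifK, against a median of 84.0 over tested genes. Of 52 ribosomal protein genes 43 fell (45 adjusted over the list alone, camera adjusted p = 0.0646), with rpl5 at -0.93 and rpl16 at -1.07. Of 17 electron transfer and ATP synthase genes 13 fell and 1 rose (camera adjusted p = 0.0646), with atpC at -0.80, petC at -0.73 and petJ at 0.30. Of 12 carboxysome and CO2 fixation genes 10 fell (11 adjusted over the list alone, camera adjusted p = 0.128), with pgk at -0.77 and glpX at -0.97. Nitrate and ammonium assimilation genes went both ways, with 5 of 19 higher and 8 lower (camera adjusted p = 0.843), ntcB at 1.42 and amtB at 0.94, and nrtA at -1.66 and nrtC at -1.97. Of 6 iron genes 1 rose and 2 fell (camera adjusted p = 0.478). schE rose by 0.33, a call lost without any 1 of WT with nitrate replicates 1, 2 and 4 or WT without nitrate replicates 1 to 3 (0.26 to 0.35). The 2 that fell were isiA at -1.54 and isiB at -1.40. The call of isiA was lost without WT with nitrate replicates 1 or 2 or without WT without nitrate replicates 1 or 3 (-1.44 to -1.09), and that of isiB without WT with nitrate replicate 2 or without WT without nitrate replicate 3 (-0.998 and -1.10). Of 13 stress genes 3 rose and 1 fell (camera adjusted p = 0.642), with dpsA at 1.63, ocp at 0.39 and flv3A at -0.43. Of 13 cell division genes 5 rose and 1 fell (camera adjusted p = 0.467), with sepF at 0.44 and ftsZ at 0.32. Of 14 peptidoglycan synthesis genes 3 rose and 1 fell (camera adjusted p = 0.843), with murB at 0.61, murC at 0.51 and murD at -0.29. Of 9 septum genes 3 rose (camera adjusted p = 0.343), with hepP at 0.56 and amiC1 at 0.35. Of the 4 flavodiiron and hydrogenase genes measured in the oxidase and hydrogenase list 3 rose (camera adjusted p = 0.171), with flv3B at 0.30 and hupS at 0.24. Of 7 inorganic carbon uptake genes 1, cupB, fell (-0.29, camera adjusted p = 0.941). Further calls were lost with 1 library left out: hupS without WT with nitrate replicate 2 or WT without nitrate replicates 2 or 4 (0.17 to 0.22), cupB without WT with nitrate replicates 3 or 4 or WT without nitrate replicate 1 (-0.26 to -0.23), and minD, the cell division gene that fell (-0.22), without WT with nitrate replicate 4 or WT without nitrate replicates 1 or 2 (-0.20 to -0.16). Counts adjusted over the list alone were the same where no second count is given. The median and the mean differed in sign for nitrate and ammonium assimilation (0.06 and -0.31), stress (-0.02 and 0.15) and peptidoglycan synthesis (-0.01 and 0.06), and the sign of the test was that of the mean. In all, 1899 genes were called, 992 higher and 907 lower, and 1866 by the authors' adjusted p, of which 1701 were shared. With libraries centred on their medians 2045 were called, 687 higher and 1358 lower.

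Removal of nitrate from CSVM34 gave 1758 called genes, 871 higher and 887 lower (1792 with centred libraries, 640 higher and 1152 lower). All 19 polysaccharide layer genes rose (19 adjusted over the list alone, median 1.40, camera adjusted p = 0.0204), led by alr2833 at 2.98, alr2827 at 2.79, alr2825 at 2.48 and alr2826 at 2.47. nrrA, a response regulator that acts early in differentiation, rose by 2.24, and 8 of 14 heterocyst regulators rose (8 adjusted over the list alone, camera adjusted p = 0.0152), among them patU3 at 1.12. The largest fall on the regularized scale was in isiA, a chlorophyll-binding protein made under iron limitation, at -3.26 (SE 0.54, limma adjusted p = 4.03e-05), with all4000 at -3.13, all4003 at -2.61, all4002 at -2.60 and the flavodoxin gene isiB at -2.63. nrtD fell by 2.45 and pecB by 2.32. All 20 phycobilisome genes fell (20 adjusted over the list alone, median -1.49, camera adjusted p = 0.0204), with apcA at -1.50 and apcB at -1.53. Of 10 photosystem I genes 9 fell (10 adjusted over the list alone, camera adjusted p = 0.0204), with psaL at -0.53 and psaA at -0.80, and of 16 photosystem II genes 12 fell (12 adjusted over the list alone, camera adjusted p = 0.0204), with psbT at -0.79 and psbD at -0.85.

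Removal of nitrate from CSVM141 gave 1493 called genes, 698 higher and 795 lower. Of 14 heterocyst regulators 7 rose and none fell (8 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.00523). nrrA rose by 2.42 and hetZ by 1.79. Of 19 polysaccharide layer genes 8 rose (9 adjusted over the list alone, median 0.23), and this list was not called (camera adjusted p = 0.381). Its 2 members with the smallest p were alr2837 at 1.16 and alr2838 at 0.83. Among the largest falls on the regularized scale were again isiA at -3.69 (SE 0.54, limma adjusted p = 1.01e-05), all4000 at -3.56, all4002 at -3.09, all4003 at -3.05 and isiB at -2.96, with pecA at -2.69 and pecB at -2.67. All 20 phycobilisome genes fell (20 adjusted over the list alone, median -1.56), as did 8 of 10 photosystem I genes (9 adjusted over the list alone) and 12 of 16 photosystem II genes (13 adjusted over the list alone), each with camera adjusted p = 0.0171. Examples were cpcG4 at -2.01, psaL at -0.64 and psbT at -0.74. Across the 3 strains, 429 genes rose in all and 491 fell in all.

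The response of each mutant was set against that of WT in tests of the difference itself. CSVM141 and WT differed in 181 genes, 63 higher and 118 lower in CSVM141 (227 with centred libraries, 127 higher and 100 lower). The polysaccharide layer genes, most of them neighbours, rose less in CSVM141: 15 of 19 were lower (17 adjusted over the list alone, median -2.18, camera adjusted p = 0.00166), with alr2827 at -4.02 and alr2825 (rfbF) at -3.91. Among the regulators hetZ was at 1.16 and patA at 1.10. CSVM34 and WT differed in 87 genes, 25 higher and 62 lower (54 genes without WT without nitrate replicate 2). Of the polysaccharide layer genes 10 were lower (14 adjusted over the list alone, median -1.19), and the list was not called (camera adjusted p = 0.0506). pecA was at 1.21 and pecB at 1.16, so both fell less in CSVM34. CSVM141 and CSVM34 differed in 16 genes, 2 higher and 14 lower, and the polysaccharide layer list was called (8 of 19 lower, 17 adjusted over the list alone, median -0.96, camera adjusted p = 0.00501). The 16 became 10 without replicate 2 of CSVM34 without nitrate, and 10 without replicate 2 of CSVM141 without nitrate.

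**Figure D2:**
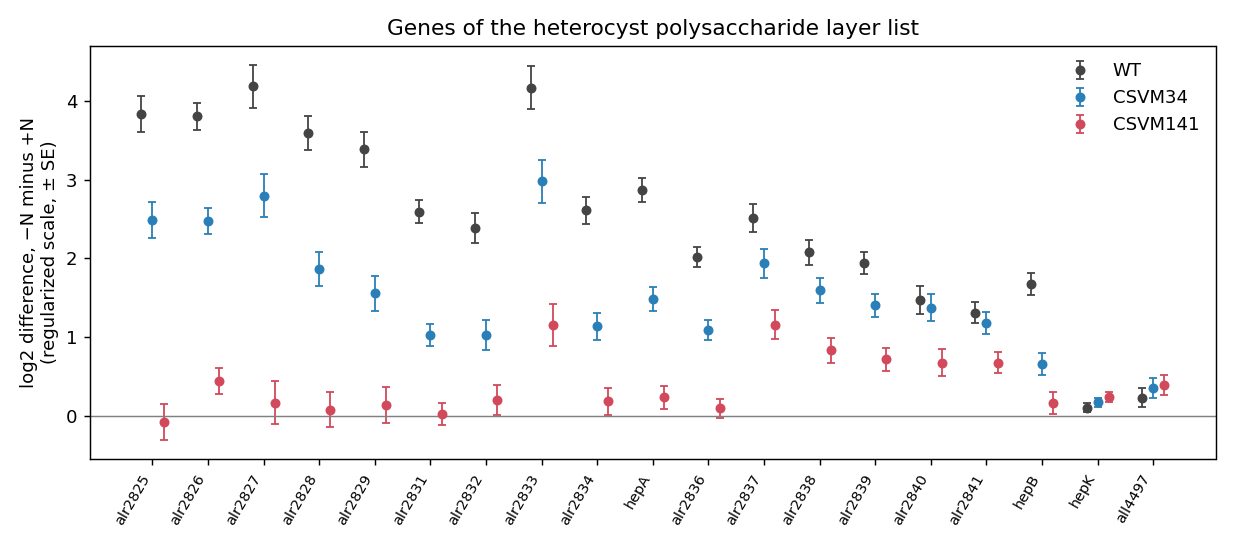
Difference in regularized log2 expression without nitrate against with nitrate for the 19 genes of the heterocyst polysaccharide layer list in each strain (points, with SE bars). The median was 2.51 in WT, 1.40 in CSVM34 and 0.23 in CSVM141.

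With nitrate, CSVM34 differed from WT in 1057 genes, 511 higher and 546 lower. Among the largest rises on the regularized scale were alr7329 at 3.08 (SE 0.20, limma adjusted p = 2.42e-11), all7030 at 2.60, sbtA, a bicarbonate transporter, at 2.57 (SE 0.88, limma adjusted p = 0.0435), alr7200 at 2.26, all4446 at 2.11 and psbAIII at 2.05. The calls of sbtA and all4446 were lost without any 1 of WT with nitrate replicates 1 to 4 or of CSVM34 with nitrate replicates 2 and 3 (1.78 to 2.64 and 1.43 to 2.25). Among the largest falls were alr3729 at -4.77 (SE 0.21, limma adjusted p = 1.28e-14) and alr3730 at -3.92, followed by the plasmid genes all7160 at -3.03, alr7163 at -2.93 and asl7159 at -2.88. No list was called. Of 20 phycobilisome genes 11 fell (13 adjusted over the list alone, camera adjusted p = 0.698), among them apcD at -0.55 and apcC at -0.31. Of 17 electron transfer and ATP synthase genes 10 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.641), with atpE at -0.40 and atpH at -0.39. In the septum list sepN fell by 0.57 and sjcF1 by 0.45 (2 of 9, and 3 adjusted over the list alone). ntcA, the global nitrogen regulator, fell by 0.67 and nifU by 0.75.

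CSVM141 with nitrate differed from WT in 1699 genes, 835 higher and 864 lower. Among genes that met the naming rule, those for inorganic carbon uptake led the rises on the regularized scale: the bicarbonate transporter genes cmpA at 3.83 (SE 0.93, limma adjusted p = 0.003) and sbtA at 3.58 (SE 0.88, limma adjusted p = 0.00329), and also sbtB at 2.84 (SE 0.70, limma adjusted p = 0.00339), with all4446 at 3.19. Of 7 measured, 6 rose (6 and 1 lower adjusted over the list alone, median 2.84). The list was not called (camera adjusted p = 0.984 with an estimated correlation of 0.83, and 0.0193 with the preset one). The mean of the 6 genes other than cupB, which were grouped after their values were seen, was 10.47 ± 1.58 in CSVM141 and 7.70 ± 0.11 in WT (SD, n = 4 each). The difference was 2.77 (exact two-sided permutation p = 0.0286, the smallest possible, 0.0857 adjusted over 9 comparisons), with all 4 libraries above all 4 of WT and replicate 1 apart (8.12 against 10.99 to 11.46). CSVM34 with nitrate (1.82) and CSVM141 without nitrate (1.28) had the same p against WT, and CSVM141 was above CSVM34 with nitrate by 0.95 (exact permutation p = 0.343). Of 13 stress genes 5 rose (6 adjusted over the list alone, camera adjusted p = 0.0944), among them the flavodiiron gene flv1A at 1.01 and htpG at 0.40. In the photosystem II list psbAII rose by 1.26 and psbAIII by 1.32. petF rose by 0.76 and petE by 0.77. sjcF1 fell by 0.48, sepN by 0.31 and ntcA by 0.75. Among the largest falls on the regularized scale were alr3729 at -4.67, alr3730 at -3.75 and the plasmid genes alr7346 at -3.53, alr7345 at -3.41 and alr7304 at -3.37.

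**Figure D3:**
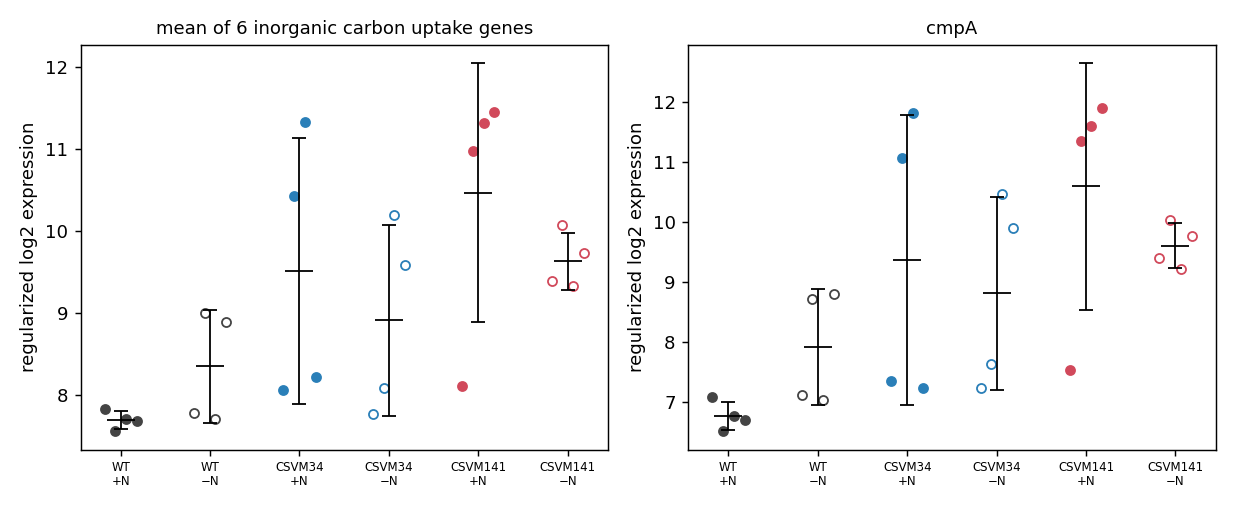
Mean regularized log2 expression of 6 inorganic carbon uptake genes, and that of cmpA, in each library (points) with group mean and SD (bars, n = 4). CSVM141 with nitrate ranges from 8.12 to 11.46, while the mean of WT with nitrate is 7.70.

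Without nitrate, CSVM34 differed from WT in 740 genes, 323 higher and 417 lower. Heterocyst envelope genes were lower. Of 19 polysaccharide layer genes 14 fell (16 adjusted over the list alone, median -1.29, camera adjusted p = 0.0375), with hepC at -1.69 and alr2831 at -1.50. The call was lost without CSVM34 without nitrate replicate 1 or CSVM141 without nitrate replicate 1 (camera adjusted p up to 0.0589). Of 14 glycolipid layer genes 7 fell (9 adjusted over the list alone, median -0.47, camera adjusted p = 0.0357), with devA of the glycolipid exporter at -0.91 and hglK at -0.72. Of the 4 measured genes of the oxidase and hydrogenase list, which are flavodiiron and hydrogenase genes, 3 fell (camera adjusted p = 0.0228), with flv3B at -0.57 and hupS at -0.34. No cytochrome oxidase gene was measured. nifU fell by 0.69 and nifV1 by 0.60. patU3 rose by 0.88, patU5 by 0.79 and the D1 gene psbAII by 0.86, and ntcA fell by 0.86. Among the largest changes on the regularized scale were alr3729 at -5.15, alr3730 at -4.11 and the plasmid genes alr7163 at -3.29 and all7030 at 3.02.

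Without nitrate, CSVM141 differed from WT in 1467 genes, 655 higher and 812 lower (1827 with centred libraries, 1256 higher and 571 lower). Of 19 polysaccharide layer genes 17 fell (17 adjusted over the list alone, camera adjusted p = 0.0409), led by alr2827 at -4.05 (SE 0.27, limma adjusted p = 3.08e-11), alr2825 at -3.74, alr2828 at -3.41 and alr2826 at -3.31. That call was lost without WT without nitrate replicate 4, CSVM141 with nitrate replicate 3 or CSVM141 without nitrate replicate 1 (camera adjusted p up to 0.0781). Of 14 glycolipid layer genes 8 fell (11 adjusted over the list alone, camera adjusted p = 0.0707), with devA at -1.11 and hglK at -0.61. Of 17 nitrogenase genes 8 fell (11 adjusted over the list alone, camera adjusted p = 0.0897), with nifU at -0.87 and nifV1 at -0.77. Many genes of this list, nifH, nifD and nifK among them, had few reads. patA, which affects where heterocysts form, rose by 1.63 (SE 0.13, limma adjusted p = 7.1e-10) and patU3 by 1.03. Of 16 photosystem II genes 11 rose (14 adjusted over the list alone, camera adjusted p = 0.0674), among them psbAII at 1.00 and psbD at 0.41. sodB, a superoxide dismutase gene, rose by 0.74. The largest falls on the regularized scale also held alr3729 at -5.02, alr3730 at -4.18 and the plasmid gene all7013 at -3.48.

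CSVM141 was also set against CSVM34 directly. With nitrate 713 genes were called, 318 higher and 395 lower, and without nitrate 941, 433 higher and 508 lower (1115 with centred libraries, 720 higher and 395 lower). Plasmid genes led in both media. With nitrate, alr7163 was at 3.84 and all7160 at 3.64, and alr7329 was at -5.35 and all7030 at -4.78. Without nitrate, alr7163 was at 3.91 and alr7127 at 3.76, and alr7329 was at -5.44 and all7030 at -4.72. Without nitrate 17 of 19 polysaccharide layer genes were lower in CSVM141 (17 adjusted over the list alone, median -0.86, camera adjusted p = 0.217), with alr2825 at -2.33 and alr2826 at -1.79. Of 17 electron transfer and ATP synthase genes 11 were higher (12 adjusted over the list alone, camera adjusted p = 0.293), with atpC at 0.67 and atpD at 0.71.

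Plasmid genes made up a large part of the strain differences of at least 1 log2, and a smaller part of all called genes. They were 12.3% of genes and 72.4% of the 232 genes that differed by as much between CSVM141 and WT with nitrate (Fisher's exact test, adjusted p = 1.64e-105), and 72.3% of 65 between CSVM34 and WT (6.88e-29). The test takes genes as independent, but many plasmid genes changed together in runs of neighbours. Its p-values therefore overstate the evidence, and the shares are descriptive. Without nitrate the shares were 67.6% of 241 and 51.3% of 78. Of all called genes with nitrate, 446 of 1699 in CSVM141 and 171 of 1057 in CSVM34 were on plasmids. Of the 170 genes that differed by as much between media in WT, 3 were on plasmids. In the authors' deposited table, runs of consecutive plasmid loci were near absent from CSVM141 in both media. The longest were the 45 genes from alr7304 to all7372 and the 43 from all7002 to alr7073 on plasmid alpha, with median log2 fold changes of -6.67 and -6.66 with nitrate in the authors' deposited table. CSVM34 had a run of its own, of 8 genes from alr7162 to all7170, at -4.91 with nitrate and -5.93 without in the authors' deposited table. On the chromosome the pair alr3729 and alr3730 was low in both mutants, at -6.29 in CSVM34 and -5.95 in CSVM141 with nitrate in the authors' deposited table. CSVM141 also had 6 genes from alr8535 to alr8543 on plasmid delta at 8.01 with nitrate and 7.74 without in the authors' deposited table. A run of 3 genes from alr8557 to all8559 on plasmid delta was higher in both mutants, at 6.32 in CSVM34 and 6.88 in CSVM141 with nitrate in the authors' deposited table.

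**Figure D4:**
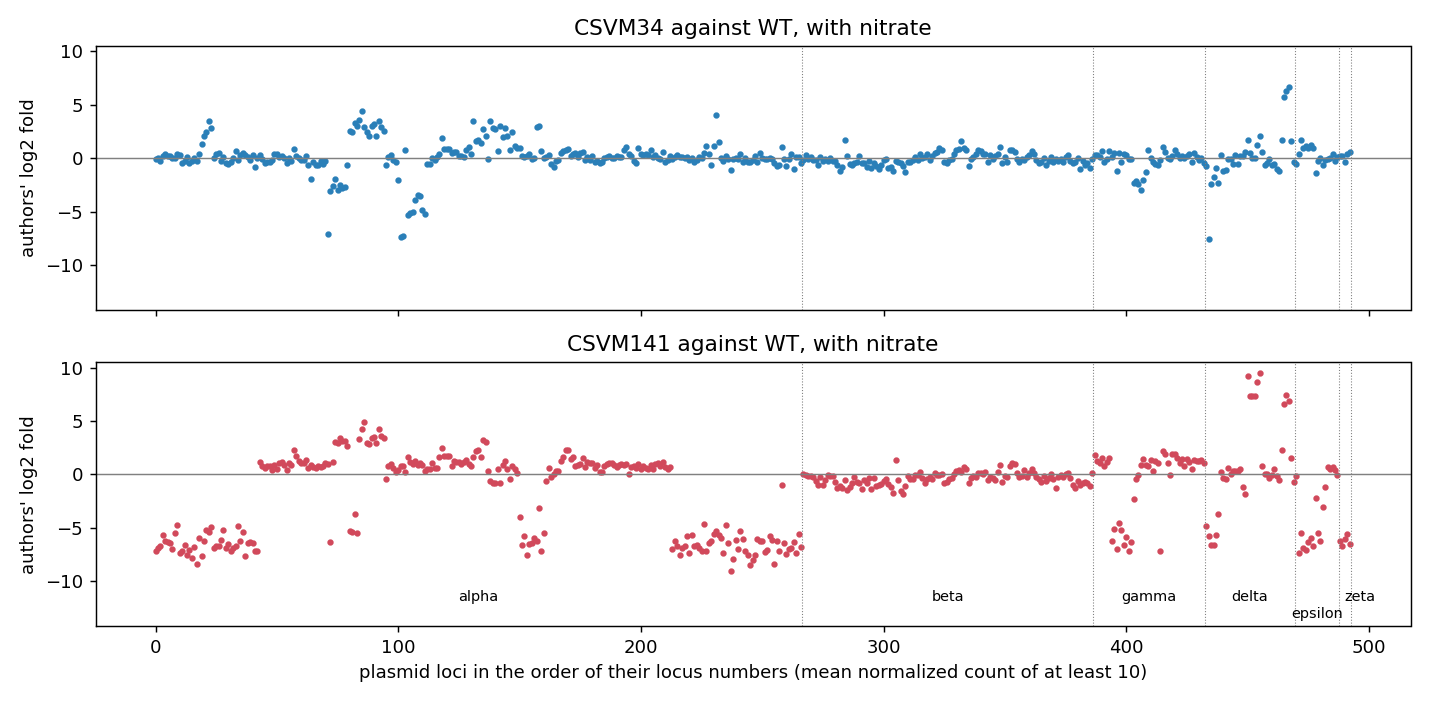
The authors' deposited log2 fold changes with nitrate of plasmid genes in the order of their locus numbers, for CSVM34 and CSVM141 against WT (points, 1 gene each, vertical lines between plasmids). In CSVM141 the longest run on plasmid alpha, of 45 genes, has a median of -6.67, and in CSVM34 a run of 8 genes has a median of -4.91.

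The mutants shared calls against the same WT libraries. With nitrate 295 genes were higher in both and 326 lower, where independent lists would share 71.2 and 78.7, and 51 went opposite ways (2 without plasmid genes). Simulated unchanged groups shared 0 and 0, which says little of sharing through WT, since such groups give almost no calls. When WT was split so that each mutant had its own 2 libraries, 141 and 156 were shared, where independent lists would share 31.1 and 35.4. The split removes only the noise of shared libraries. A trait common to all WT libraries would still be shared, so it cannot tell a likeness of the mutants from a peculiarity of WT. The covariance of the differences was 0.0622, and 0.00717 in simulated unchanged groups, while their correlation across genes, which are not independent replicates, was 0.449 and 0.490 in simulated unchanged groups. Without nitrate 171 were higher in both and 271 lower (35.3 and 56.5 for independent lists) and 49 went opposite ways (2 without plasmid genes), with a correlation of 0.377 and 0.501 in simulated unchanged groups.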

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

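The tests of the plasmid runs were chosen after the result was seen, except that of the low genes inside them. The tests of the polysaccharide layer genes, except the slope over other genes, those of the inorganic carbon uptake genes and the splits with the strain difference removed were also chosen after the result was seen.

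Runs of consecutive plasmid genes were near absent from CSVM141. There were 9 runs with 138 genes, at a median of 1.15% of the WT level with nitrate and 0.523% without, in ratios from the authors' deposited table, and the longest held 45 genes where shuffled orders gave at most 12. A lower copy number of the whole plasmid is argued against for plasmid alpha by its 157 genes outside the runs with a mean count of at least 10, whose median log2 fold change was 0.75 without nitrate and 0.92 with it in the authors' deposited table (0.48 and 0.64 over all 260 outside the runs). These medians are raised by taking out the runs. Of all 371 genes tested on plasmid alpha, 126 were called higher in CSVM141 than in WT with nitrate and 156 lower (105 and 167 without). All 5 genes of plasmid zeta lie in a run, so its loss as a whole stays open. Loss of sepJ alone is argued against by CSVM34, where the run genes were at a median of 0.11 without nitrate, although the run from alr8502 to alr8509 on plasmid delta was lower there too, at -2.05 with nitrate and -1.60 without in the authors' deposited table. DNA missing from the strain may account for the runs, since the 67 genes inside them too low to be used in finding them summed to 4.76% of WT with nitrate and 3.77% without. RNA cannot tell missing DNA from shut-off of whole regions, and whether the strain's history or the deletions lie behind it was not tested.

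The polysaccharide layer genes rose less in CSVM141 than in WT on removal of nitrate. Shrinkage of the values is argued against by the authors' deposited table, where the median response of the list was lower in CSVM141 than in WT by a log2 difference of -3.69. A weaker response over all genes is argued against as the whole cause by slopes of the CSVM141 response on the WT response. The slope was 0.126 over the list, fitted through 0 (0.104 to 0.159 with 1 library left out). It was 0.701 over 1847 other genes called in WT, fitted with an intercept (0.680 to 0.725). The fits are not alike, so only the large gap between the slopes is read. Whether a weaker response over all genes is part of the cause stays open, since 0.701 lay between the bounds of 0.5 and 0.75 set before it was seen. Fewer or later heterocysts with early steps kept stays open, since the regulators' differences in response went both ways around a median of 0.0534 (-0.35 to 1.16, with hetZ at 1.16 and patA at 1.10) and no count of heterocysts was used here.

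Inorganic carbon uptake genes split the libraries of single groups. With nitrate, cmpA was at 7.35, 11.07, 11.83 and 7.23 in the 4 CSVM34 libraries and at 7.53, 11.35, 11.60 and 11.91 in those of CSVM141. A swap of whole libraries between strains or media is argued against, since 0 of 24 libraries carried another strain's sepJ, plasmid runs or another medium's phycobilisome level. Each mark was read only by its side of a midpoint, so this cannot decide on a partly mixed library. In CSVM141 with nitrate, replicate 1 had the highest sepJ (6.26 against 5.76 to 5.90) and fraD (5.14 against 4.52 to 4.78) of its group. Its fraC was not the highest (4.37 against 4.09 to 4.69). Strain stays open as a part: with nitrate the lowest CSVM141 library lay 0.28 log2 above the highest of WT in the mean of 6 genes, but a split within a strain needs a further cause. Handling of the samples in runs of 6 consecutive titles could be one and cannot be told apart from chance with 4 runs (permutation p = 0.0908 over 100000 permutations), with mean deviations of -0.94, 0.26, 0.51 and 0.17 from the group means and replicate 1, which is the first run, below its group mean in 5 of 6 groups.

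Other single libraries lay far from the other 3 of their group, by the gap to the nearest as a share of the range, among 6 genes, 18 list means and the library median. In 150 groups 8 did so (5.33%), where chance gives about 1 in 20. sepJ was at 6.54 in CSVM141 without nitrate replicate 1 and 6.01 to 6.09 in the others (gap 0.849). fraC was at 4.95 in WT with nitrate replicate 1 against 5.38 to 5.46 (0.844), and fraE there at 7.67 against 7.39 (0.997). The mean of nitrate and ammonium assimilation was 8.16 in WT without nitrate replicate 2 against 8.46 to 8.52 (0.849). Inorganic carbon uptake was at 8.02 in CSVM141 with nitrate replicate 1 against 10.51 to 10.89 (0.868). That library was also apart over all genes. Its root mean square deviation from the group mean was 0.268 log2, against 0.128 to 0.169 in the others of its group. Photosystem I was at 13.28 in WT with nitrate replicate 1 against 13.21 (0.885), and stress at 7.82 in CSVM141 with nitrate replicate 2 against 7.95 to 7.97 (0.887). The library median was 6.39 in CSVM34 without nitrate replicate 2 against 6.37 (0.912).

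Responses that differed between strains numbered 87 genes for CSVM34 and WT, 181 for CSVM141 and WT and 16 for CSVM141 and CSVM34. In CSVM34 against WT, the response was higher for pecA by 1.21, pecB by 1.16, alr4685 by 1.01, pecC by 0.96 and alr4686 by 0.88. It was lower for alr2829 (-1.83), alr2828 (-1.73), alr2824 (-1.61), alr2831 (-1.57) and alr7204 (-1.55). The call of pecC was lost without any 1 of 12 of the 16 libraries, which were all but WT with nitrate replicate 2, WT without nitrate replicate 1, CSVM34 with nitrate replicate 1 and CSVM34 without nitrate replicate 4 (0.83 to 1.00). In CSVM141 against WT it was higher for hetZ by 1.16, patA by 1.10, asr0098 by 1.08, alr4939 by 1.02 and alr0103 by 0.93, and lower for alr2827 (-4.02), alr2825 or rfbF (-3.91), alr2828 (-3.51), alr2826 or lhgO (-3.36) and alr2829 (-3.25), with the polysaccharide layer list at a median of -2.18. In CSVM141 against CSVM34 it was higher for alr1554 by 0.98 and all5222 by 0.60, and lower for alr2827 (-2.63), rfbF (-2.56), lhgO (-2.03), alr2833 (-1.82) and alr2935 (-1.25), with the list at -0.96. The call of alr2833 was lost without any 1 of CSVM34 with nitrate replicates 2 to 4, CSVM34 without nitrate replicates 2 and 4, CSVM141 with nitrate replicates 1 to 3 and CSVM141 without nitrate replicates 1 and 2 (-1.86 to -1.54). That of alr2935 was lost without any 1 of CSVM34 with nitrate replicates 1 and 4, CSVM34 without nitrate replicates 2 and 4, CSVM141 with nitrate replicates 3 and 4 and CSVM141 without nitrate replicates 1, 2 and 4 (-1.26 to -1.13).

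Chance is argued against for the counts of called genes in all 9 comparisons of 2 groups, since 1 of the 35 splits of each 8 libraries, the real one, gave as many. No smaller share is possible with 35 splits. If replicates are technical, the splits cannot tell strain or medium from other differences between cultures. The highest count of another split, beside the real one, was 14 beside 1899 for WT between media, 24 beside 1758 for CSVM34, 120 beside 1493 for CSVM141, 36 beside 1057 and 426 beside 1699 for CSVM34 and CSVM141 against WT with nitrate, 1 beside 740 and 12 beside 1467 without nitrate, and 338 beside 713 and 1 beside 941 for CSVM141 against CSVM34. Chance is argued against for the number of called lists in the same way and with the same limits, with 1 of 35 splits: 5 lists and at most 0 in another split for WT between media, 5 and 1 for CSVM34, 4 and 0 for CSVM141, 3 and 1 for CSVM34 against WT without nitrate, and 1 and 0 for CSVM141 against WT without nitrate. For differences in response, 3 of 100 splits gave as many genes as the 87 (highest other 518), 4 of 100 as the 181 (1299) and 9 of 100 as the 16 (785). Splits that call many more genes point to a structure of the samples: they divide the strains unequally, so strain differences enter. For that reason these splits cannot decide on chance for any of the 3 counts. With the mean strain difference removed, 1 of 100 splits, the real one, gave as many in each, with highest others of 10, 82 and 1. Chance is argued against for the 3 counts by these later splits alone. In the splits without that removal, 4 of 100 gave as many called lists for CSVM141 and WT (1 and at most 4 in another) and 1 of 100 for CSVM141 and CSVM34 (1 and 0). These are counts of any of the lists, and strain differences enter them. They therefore cannot decide on chance for the polysaccharide layer list itself.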

How the results depend on the processing

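The authors' adjusted p-value, the count minimum, the fit without the trend, the centring and the fit without plasmid genes were chosen after seeing the data. A minimum log2 difference of 1 left 170, 148 and 113 genes between media in WT, CSVM34 and CSVM141, 65 and 232 for CSVM34 and CSVM141 against WT with nitrate and 78 and 241 without, 184 and 201 for CSVM141 against CSVM34 with and without nitrate, and 20, 50 and 9 for differences in response of CSVM34 and WT, CSVM141 and WT, and CSVM141 and CSVM34. Without plasmid genes, which leaves fewer genes to test, 933 genes were called for CSVM141 against WT without nitrate, and 235 and 474 for CSVM141 against CSVM34 with and without nitrate. The 20 called lists became 85 with the preset correlation and 91 with fry. The first does not use the estimated correlation, and fry does not compare a list with other genes. Leaving out 1 library gave 1671 to 1827, 1459 to 1627 and 1242 to 1530 genes between media, 808 to 1055 and 1429 to 1686 against WT with nitrate, 577 to 680 and 1216 to 1381 without, 594 to 889 and 750 to 842 for CSVM141 against CSVM34, and 54 to 98, 122 to 207 and 10 to 17 for differences in response, where 54 was without WT without nitrate replicate 2 and 10 without CSVM34 or CSVM141 without nitrate replicate 2. It gave 18 to 33 lists, with 33 without WT without nitrate replicate 3. No called value of a named gene reversed under any setting run. Of 1057 such values, 108 were not called with only the libraries compared, 51 with centred libraries and 32 without the trend, and of 9056 values with 1 library left out 1037 were not called. The cause of these losses was not tested. The replicate block by runs of 6 consecutive titles, which the labels do not tie to a shared batch, gave 2016, 1895 and 1661 genes between media, 129, 264 and 15 for differences in response, and 28 lists, of which 19 were among the 20. It ended the call of 2 of the 1057 values and that of the polysaccharide layer list for CSVM141 against WT without nitrate (camera adjusted p = 0.0512). Over 60 pairs within a run, deviations from group means had a median correlation of 0.12 (-0.29 to 0.47), with 15 of 24 libraries correlating best with their own run. Alternatives that need raw counts (other size factors, library totals, another count model and read filters) and other pseudocounts were not run. What depth limits was not tested, as the depth of each library is unknown, and genes with few reads have regularized values pulled toward their mean.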

Other observations

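Several genes of the nitrogen response rose or fell in all 3 strains. The nitrogen regulator gene ntcB rose by 1.42 in WT, 1.43 in CSVM34 and 1.58 in CSVM141 on removal of nitrate, and the ammonium transporter gene amtB by 0.94, 1.04 and 1.27. hesA of the nitrogenase cluster rose by 1.87, 1.84 and 1.56. dpsA, a DNA-binding protein of starved cells, rose by 1.63, 1.70 and 1.29. On the same change nrtA fell by 1.66, 1.78 and 1.48. Of 14 glycolipid layer genes 9 rose in WT, 5 in CSVM34 and 2 in CSVM141, and the list's difference in response between CSVM141 and WT was not called (camera adjusted p = 0.0531).

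Some genes of cell division and of the cell wall were called. sepF rose by 0.44 in WT and 0.57 in CSVM34 on removal of nitrate, and murC rose by 0.51, 0.47 and 0.45 in the 3 strains. With nitrate murA was higher than in WT by 0.25 in CSVM34 and 0.45 in CSVM141. Of the plasmids, the whole of zeta, 5 genes from asr9501 to alr9505, was among the runs near absent from CSVM141. Libraries were separated along components that held 36.6%, 28.1% and 12.2% of the variance.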
